A study of Mus musculus with 2 samples.

How the data were processed

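Sorted white blood cells from red-cell-lysed mouse blood were loaded on a droplet system with 3' chemistry, 26500 cells per library, per the labels' protocols. The authors deposited 2 tables of the same 2260 monocyte cells and 28693 gene rows, among them a row for the reporter eGFP-Cre. The first holds raw UMI counts, and the counts were deposited without normalization. The second holds scaled scores that the authors computed per gene and deposited; they run from -17.3 to 10, and 7935 of 14187 rows that were not constant had an SD of 1 within 0.001. How these scores were made is not given in the sources used here. Per the submitters' processing notes, Cell Ranger, Seurat 3.1 and the mm10 build were used, with no roles stated. How the monocytes were chosen from all cells obtained is not given either. In the deposited counts no cell had more than 2499 genes or more than 4.84% mitochondrially encoded UMIs.

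Column prefixes assigned each cell to the wild-type or the Lyn -/- library. All 28693 rows were kept, and 14187 held a UMI. Cells were clustered with scanpy 1.11.5 (Python 3.11.15) on log-normalised counts, using 2000 genes variable within the libraries, 30 principal components, 15 neighbours and Leiden resolution 0.5. Lyn, sex-linked, reporter, ribosomal, mitochondrial and haemoglobin genes were left out of the clustering. Clusters were named from markers fixed before the data were examined, by the highest mean log2 fold of a kind's markers. By a threshold set with the data at hand, a cluster with at least 3 markers of another cell type over 4-fold above the remaining cells was kept out of the monocyte classes. The clusters so kept out, with neutrophil, platelet, T cell and B cell genes, held 7, 2, 2 and 8 wild-type and 88, 17, 28 and 2 Lyn -/- cells. Names are "-like" because they rest on rebuilt clusters. A cluster led by interferon genes, with 12 wild-type and 6 Lyn -/- cells, was counted as classical-like. No doublets were removed in the main values. Scrublet called 13 wild-type and 11 Lyn -/- cells, and their removal was an alternative. The nonclassical-like and classical-like classes were fixed for comparison beforehand. Any further class needed at least 200 cells in each library, and the MHC class II class, with 161 and 113, was left out of the main comparisons of genes. Its shares and list medians are given, and values of some of its genes stand among the closing observations.

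UMIs were summed over the cells of a class in each library and expressed as CPM of the class's summed UMIs. Log2 ratios of the Lyn -/- over the wild-type library were taken with 0.5 UMI added to each sum. Their 95% intervals are exact conditional binomial intervals, and shares have exact Clopper-Pearson intervals. Intervals of differences between classes are normal approximations from the UMI counts. All cover counting error only, not differences between mice, pools or library preparations. Those of log2 ratios also do not cover variation between cells. Named genes were the 12 highest and 12 lowest by the interval bound nearest to 0, among genes with at least 100 UMIs over both libraries and at least 50 CPM in 1 or both. Lyn, sex-linked, haemoglobin, immunoglobulin and T cell receptor genes were left out of this rule, and up to 4 members of each gene list were named by the same bound. Some members that this would name are not reported here. A list's median was taken over members with at least 20 UMIs, placed among 10000 random lists matched on expression in 20 bins, and given an interval from 1000 Poisson resamplings. The summed UMIs were 1179371 and 4334803 in nonclassical-like cells of the wild-type and Lyn -/- libraries, and 1537244 and 911240 in classical-like cells.

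The intervals were tried on simulated Poisson counts with 200 genes changed, the model that they assume. This checks the calculation only, since variation between cells beyond counting error was not simulated. In the nonclassical-like setting, over 5621 genes, 95.4% of unchanged genes had an interval that held 0, and the interval left out 0 on the true side for 79.1% of genes changed 1.5-fold and 100% of those changed 2-fold. In the classical-like setting, over 3049 genes, these values were 96.4%, 80.6% and 98.5%. Gene positions came from GENCODE M21 on GRCm38, the assembly of mm10, in which 27337 of the 28693 row names were found.

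Alternatives fixed before the data were examined were scaling by edgeR 4.0.16 TMM factors or DESeq2 1.42.0 size factors, scaling without ribosomal, mitochondrial and haemoglobin UMIs, the mean of per-cell CPM, cells thinned to 2500 UMIs, 5 UMIs added, other UMI minimums, a filter on cells, doublet removal, Leiden resolutions 0.3 and 1.0, placement by markers, clustering without differing genes and another denominator. Chosen after seeing the data were Xist cells alone, Y cells alone, each nonclassical-like cluster alone, the 2% of cells with the most UMIs of each gene left out, and the direction of the scaled scores. Xist and Y cells are kinds read from the counts, not groups of the labels, and sex and reporter cannot be separated in them.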

Results

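The series profiled blood monocytes of mice with and without Lyn, a Src family tyrosine kinase, by droplet single-cell RNA sequencing. Per the labels, white blood cells of C57BL/6 and Nr4a1-eGFP/cre reporter mice were pooled in equal numbers for the wild-type library. Cells of Lyn -/- and reporter Lyn -/- mice were pooled in the same way for the knockout library. Each genotype was therefore measured in 1 library, and the number of mice is not given in the sources used here. Of 10859 cells obtained for the wild-type library, 767 were in the deposited tables, and of 11093 obtained for the Lyn -/- library, 1493 were. The deposited cells held 3672039 unique molecular identifiers (UMIs) in the wild-type library, with a median of 4644 per cell, and 6605811 in the Lyn -/- library, with a median of 4165. Within classes the Lyn -/- median was the higher one. It was 3906 against 3579 in nonclassical-like, 6458 against 5969 in classical-like and 5940 against 5333 in MHC class II cells. With 1 library per genotype there was no replicate check and no test. The values below compare 2 libraries, and their 95% intervals cover counting error only.

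Lyn UMIs were almost absent from the Lyn -/- library. In nonclassical-like monocytes Lyn stood at 611 CPM (UMIs per 1000000 UMIs of the class; 721 UMIs) in the wild-type library and at 2.77 CPM (12 UMIs) in the Lyn -/- library, a log2 ratio of -7.73 (95% interval -8.75 to -6.97). In classical-like monocytes it stood at 562 CPM against 3.29 CPM (3 UMIs), a log2 ratio of -7.19 (-9.70 to -5.86). The gene lies on chromosome 4 from 3678115 to 3813122 in mm10, on the plus strand. Which part of it is deleted is not given in the sources used here, and 3' tags from outside that part would check nothing. Of the other Src family kinases measured in nonclassical-like cells, Fyn was higher in the Lyn -/- library (log2 ratio 0.81, 0.56 to 1.07). Fgr had a log2 ratio of 0.30 (0.15 to 0.44), but -0.019 among cells with Y-linked UMIs. In classical-like cells the intervals of Fyn and Fgr held 0. Genes near Lyn on chromosome 4 had a median log2 ratio of 0.15 in nonclassical-like cells, -0.016 among Xist cells (defined with the shares), and of 0.23 in classical-like cells, with an interval that held 0.

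The series title names monocyte subset heterogeneity as its subject, and the first comparison was of subset composition. Nonclassical-like cells made up 80.3% of monocyte-like cells in the Lyn -/- library (1091 of 1358 cells, exact binomial interval 78.1 to 82.4) and 42.9% in the wild-type library (321 of 748, 39.3 to 46.6). Classical-like cells made up 11.3% (9.70 to 13.1) in the Lyn -/- library and 35.6% (32.1 to 39.1) in the wild-type library. A further class, led by major histocompatibility complex (MHC) class II genes, made up 8.32% and 21.5%. Clustering without the 2133 genes that differed over 1.5-fold between the libraries gave nonclassical-like shares of 84.0% in the Lyn -/- library and 53.8% in the wild-type library. In that clustering the MHC class II class and the clusters with platelet, T cell and B cell genes did not form. Cells kept out of the main shares could therefore enter these shares.

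The pools mixed donors, so the shares were also taken within each kind of donor. Reporter UMIs (eGFP-Cre) were found in 36.9% of wild-type and 53.9% of Lyn -/- cells that held Xist UMIs and no Y-linked UMI, here called Xist cells. Among cells with Y-linked UMIs and no Xist UMI, here called Y cells, 1 of 222 wild-type and 1 of 275 Lyn -/- cells held reporter UMIs. A further 41.8% of wild-type and 33.7% of Lyn -/- monocyte-like cells held neither Xist nor Y-linked UMIs. Their median UMIs, 4185 and 3646, were lower than those of both kinds, and values within kinds leave them out. Among Xist cells the nonclassical-like share was 85.3% (82.3 to 88.1) in the Lyn -/- library and 41.7% (34.9 to 48.8) in the wild-type library. Among Y cells it was 73.8% (68.2 to 78.9) and 41.9% (35.3 to 48.7). The cells had been sorted, by a gate not given in the sources used here, and no deposited cell had more than 2499 genes. Of classical-like and MHC class II cells together, 21.7% in the Lyn -/- library and 13.3% in the wild-type library lay within 200 genes of that limit. For nonclassical-like cells these values were 5.68% and 1.56%.

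**Figure D1:**
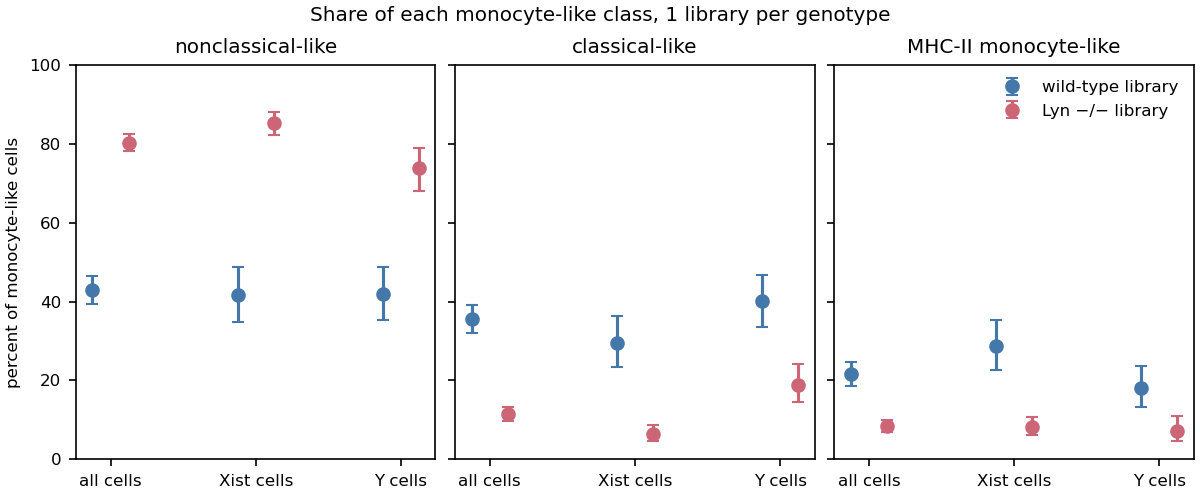
Percent of monocyte-like cells in each of the 3 classes (vertical axis, 0 to 100) for the wild-type and Lyn -/- libraries, over all cells, Xist cells and Y cells; points are shares of 1 library and bars are exact 95% binomial intervals. The nonclassical-like share lies higher in the Lyn -/- library in each panel group, at 80.3% against 42.9% over all cells.

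Within nonclassical-like monocytes, the 2 inducible Hsp70 genes led the genes that were higher in the Lyn -/- library. Hspa1b stood at 306 CPM against 36.5 in the wild-type library, 8.30-fold higher (log2 ratio 3.05, 2.63 to 3.54), and Hspa1a at 176 against 19.5 CPM (log2 ratio 3.15, 2.58 to 3.84). Handling of the libraries and genotype cannot be told apart for these genes. Tnip3, an inhibitor of NF-kB signalling, was 10.5-fold higher (3.39, 2.57 to 4.53). Cd14, the lipopolysaccharide co-receptor, was 4.79-fold higher (2.26, 1.54 to 3.20). On the lower side, Serpinb2, plasminogen activator inhibitor type 2, was 4.61-fold lower (-2.21, -2.64 to -1.77), and Hpgd, the enzyme that inactivates prostaglandins, was 2.64-fold lower (-1.40, -1.52 to -1.28).

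Further genes higher in the Lyn -/- nonclassical-like cells were Lpl, lipoprotein lipase (log2 ratio 1.90), Sash1 (2.03), Gk, glycerol kinase (1.65), and Ms4a6d (1.56). The lectin receptor Clec4e (Mincle) had a log2 ratio of 1.44 (1.18 to 1.72), the adhesion molecule Pecam1 one of 1.71, and the transcription factor Jun one of 1.30 (1.15 to 1.47). The reporter eGFP-Cre had a log2 ratio of 1.48, and of 1.06 among Xist cells. Lower in the Lyn -/- cells were Cd74, the MHC class II invariant chain (-1.16, -1.26 to -1.06), Pglyrp1 (-0.80), the ERK phosphatase gene Dusp6 (-0.89), lysozyme Lyz2 (-0.63), Rpl29 (-0.73), Gm9843 (-0.78) and Evi2a (-0.88). Cd74 was at -0.82 among Xist cells and at -0.79 among Y cells. For 3 further genes the direction over all cells did not hold in 1 or both kinds of donor cells. Fcgr3 had a log2 ratio of -1.07 over all cells but 0.027 among Y cells, and Ly6a one of -1.04 but 0.92 among Y cells. Ccl5 had a log2 ratio of -1.72, but 0.0014 among Xist cells, with an interval that held 0, and Y cells held too few UMIs for a value (3 and 10). Of its wild-type UMIs in the class, 1 cell held 48.6%. Nr4a1, Pglyrp1 and Cd74 were among the markers that named the classes. UMIs that cells may carry over from other cells were not estimated, for Cd74 or any other gene.

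Immediate early genes, which respond within minutes to many stimuli, were higher as a group. Of 20 measured members, 9 were at least 1.5-fold higher and 0 at least 1.5-fold lower in the Lyn -/- nonclassical-like cells. Their median log2 ratio was 0.54 (0.49 to 0.67), at percentile 100 among 10000 random lists matched on expression. Among them Fos had a log2 ratio of 0.95, Dusp1 one of 0.88 and Nr4a1, the nuclear receptor that nonclassical monocytes need, one of 0.97 (0.90 to 1.04). Within donor kinds the Nr4a1 ratio was lower, 0.59 among Xist cells and 0.58 among Y cells. Genes of the NF-kB response had a median of 0.66 (0.55 to 0.87, percentile 100), with 12 of 21 at least 1.5-fold higher and 1 lower. Tnfaip3 (1.68), Nfkbiz (1.08) and Ccl3 (1.33) were examples. Within each of the 2 nonclassical-like clusters alone the NF-kB median was lower, 0.36 in the cluster with most wild-type cells and 0.34 in the cluster with most Lyn -/- cells, and Ccl3 had a log2 ratio of -0.31 in the former. Heat shock genes had a median of 0.47 (0.38 to 0.62), with 4 of 10 at least 1.5-fold higher. Hsp90aa1 (0.69) and Dnaja1 (0.63) were among these 10. That median was 0.34 among Xist cells and 0.90 among Y cells.

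Because the title names lifespan, survival and death genes were listed beforehand. Pro-survival genes had a median log2 ratio of 0.27 in nonclassical-like cells (0.20 to 0.51, percentile 98.0), with 3 of 17 at least 1.5-fold higher. Pim1 (0.87, 0.71 to 1.04) was among these. Bcl2 (0.56, 0.33 to 0.80) and Bcl2a1a (0.47, 0.29 to 0.66), which has near-identical copies, were higher by less than 1.5-fold. The pro-survival median was 0.18 with DESeq2 size factors and 0.048 in the nonclassical-like cluster with most Lyn -/- cells, where Bcl2a1a had a log2 ratio of -0.040. Pro-apoptotic genes had a median of 0.22 (0.057 to 0.37, percentile 94.9), with 3 of 21 at least 1.5-fold higher. Bbc3, which lay under that size, had a log2 ratio of 0.57 (0.19 to 0.99). Integrins and adhesion genes had a median of 0.22, among them Cd9 (0.90) and Itga4 (0.55). Chemokine and trafficking receptors had one of 0.34, and of 0.13 among Xist cells and 0.21 among Y cells. Among them were the formyl peptide receptors Fpr1 and Fpr2 (1.24 and 1.25) and C5ar1 (0.98). Classical monocyte genes had a median of -0.24 (-0.51 to 0.21), -0.058 among Xist cells and -0.10 among Y cells, with Ccr2 at -0.85 and Plac8 at -0.54, but Hp, haptoglobin, at 1.25. Type I interferon genes had a median of 0.081, with an interval that held 0, and of -0.29 among Xist cells and 0.28 among Y cells.

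In the same cells, mitochondrially encoded genes had a median log2 ratio of 0.35 (0.29 to 0.41) and cytosolic ribosomal protein genes one of -0.24 (-0.25 to -0.22). Lymphocyte genes, markers of other cells, had a median of -0.54, with Igkc at -2.03. Neutrophil genes had one of 0.34 (0.017 to 0.62), with S100a8 at 0.58 (0.14 to 1.07), but of -0.18 among Y cells, where S100a8 was at -0.61. Different clusters held the class in the libraries. Of the wild-type cells 71.0% lay in a cluster led by Pglyrp1, Ccl5 and Hpgd, and of the Lyn -/- cells 86.5% lay in one led by Cd300e, Dusp16 and Hspa1b among others. Within the first cluster 24 of 24 named genes kept their direction, and within the second 23 of 24, with Ccl5 the exception. The genes were named from these same cells, so a kept direction is little evidence. Hspa1a and Hspa1b, side by side on chromosome 17 (34969190 to 34972156 and 34956436 to 34959238, minus strand, mm10), are near-identical, so the division of UMIs between them is uncertain.

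**Figure D2:**
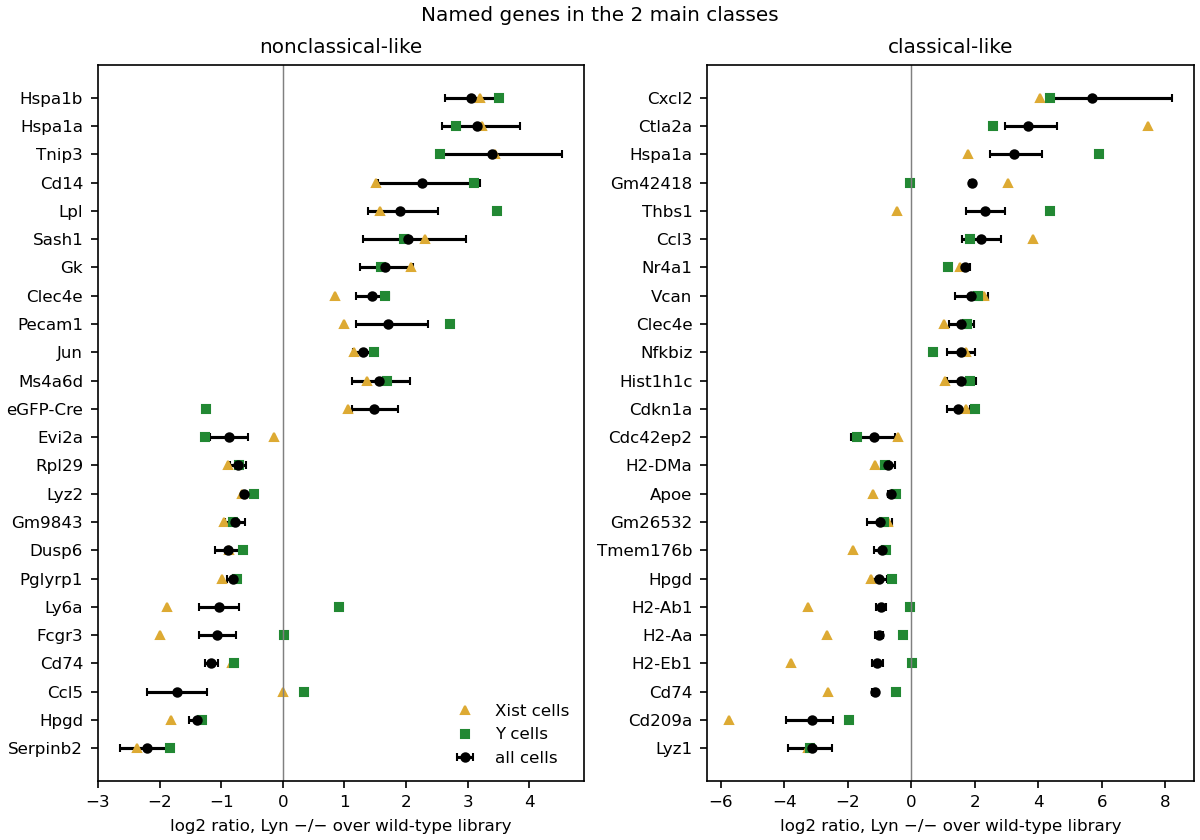
Log2 ratio of the Lyn -/- over the wild-type library (horizontal axis) for the 24 named genes of the nonclassical-like (left) and classical-like (right) classes; black points are all cells with 95% counting intervals, triangles Xist cells and squares Y cells. Hspa1b lies at 3.05 over all nonclassical-like cells, and Ccl5, Fcgr3, Ly6a and eGFP-Cre have a donor kind on the other side of 0, eGFP-Cre on 1 UMI in each library and Ccl5 among Y cells on 3 and 10.

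In classical-like monocytes the medians of the immediate early and NF-kB lists were higher in the Lyn -/- library, and that of the MHC class II list was lower. Cxcl2, a neutrophil chemoattractant, stood at 116 CPM against 1.95 in the wild-type library (log2 ratio 5.68, 4.31 to 8.20), but 1 Lyn -/- cell held 40.6% of its UMIs there. Ccl3 was 4.54-fold higher (2.18, 1.60 to 2.83), and Nr4a1 3.20-fold higher (1.68, 1.52 to 1.84). Hspa1a was 9.36-fold higher (3.23, 2.49 to 4.13). Its near-identical copy Hspa1b had a log2 ratio of 1.90 (1.27 to 2.59), but -1.19 among Xist cells. Lower were Lyz1 (-3.12, -3.89 to -2.50), which resembles Lyz2, and Cd209a, a lectin of monocyte-derived dendritic cells (-3.12, -3.93 to -2.47). In the Lyn -/- library 1 cell held 77.8% of the 18 Cd209a UMIs of the class. Lyz1 UMIs were found in 27 of 266 wild-type and 14 of 154 Lyn -/- cells, and 1 wild-type cell held 25.6% of the 301 wild-type UMIs.

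Also higher in Lyn -/- classical-like cells were Vcan, versican (log2 ratio 1.89, 1.39 to 2.43), Clec4e (1.58), Nfkbiz (1.56), the linker histone Hist1h1c (1.57) and the cell cycle inhibitor Cdkn1a (1.48, 1.12 to 1.85). Ctla2a (3.68), which is among the 10 leading genes of the cluster with platelet genes, and Thbs1, thrombospondin (2.31), were higher too, but Thbs1 had a log2 ratio of -0.44 among Xist cells. Gm42418 had a log2 ratio of 1.90, of -0.049 among Y cells, and 1 Lyn -/- cell held 53.8% of its UMIs in that library's class. Without the 2% of cells with most of its UMIs its log2 ratio was -0.28. Besides Cd74 (-1.14), H2-Aa (-1.01), H2-Ab1 (-0.94), H2-Eb1 (-1.07) and H2-DMa (-0.72), Hpgd (-1.01), Tmem176b (-0.93), Apoe (-0.64), Gm26532 (-0.98) and Cdc42ep2 (-1.16) were lower. Among Xist cells H2-Aa was at -2.66 and H2-Ab1 at -3.25, but among Y cells at -0.26 and -0.043, the latter with an interval that held 0. Cd74 and H2-DMa were at -0.49 and -0.82 among Y cells, and at -2.62 and -1.14 among Xist cells. Nr4a1, Vcan, Cd74, Cd209a and the H2 genes named here were among the class markers, and Cd209a is among the leading genes of the larger classical-like cluster.

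The MHC class II presentation list had a median log2 ratio of -0.72 (-0.96 to -0.52) in classical-like cells, with 6 of 11 members at least 1.5-fold lower and 1 higher. That median was -2.62 among Xist cells and -0.10 among Y cells. It was -0.32 when cells were clustered without differing genes, where no MHC class II class formed. Cd209a UMIs were found in 39 of 266 wild-type and 4 of 154 Lyn -/- classical-like cells. At Leiden resolution 1.0 a cluster led by H2-Eb1, H2-Aa, H2-Ab1 and Cd209a, with 82 wild-type and 42 Lyn -/- cells, was named MHC class II. The median therefore does not separate the mix of cells within the class from expression per cell. H2-Eb1 was at -3.78 among Xist cells and at 0.028 among Y cells. Immediate early genes had a median of 0.84 (0.74 to 0.94, percentile 100), with 13 of 20 at least 1.5-fold higher, among them Nr4a2 (4.09), Egr1 (2.43) and Jun (1.15). The NF-kB list had a median of 0.61 (0.46 to 0.87, percentile 100), with 12 of 22 at least 1.5-fold higher, among them Ier3 (2.70). Both medians lay above 0 within both donor kinds, the NF-kB median at 1.13 among Xist cells and 0.59 among Y cells. Heat shock genes had a median of 0.48 (0.24 to 0.74), but -0.16 among Xist cells (39 Lyn -/- cells) and 1.05 among Y cells.

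Pro-survival genes had a median log2 ratio of 0.087 in classical-like cells (-0.077 to 0.39), although Pim1 was higher (1.26, 1.07 to 1.45) and so was Mcl1 (0.45, 0.33 to 0.57). Pro-apoptotic genes had a median of -0.055 (-0.21 to 0.13). Monocyte transcription factors had a median of 0.25 (0.13 to 0.38, percentile 99.8). Mitochondrially encoded genes had one of 0.39 and cytosolic ribosomal protein genes one of -0.12. Neutrophil genes, markers of other cells, had a median of 0.87 over 4 measured members, with S100a8 at 1.60 and S100a9 at 1.64, and lymphocyte genes one of -1.47. The class rested on 266 wild-type and 154 Lyn -/- cells, of which 95.5% and 96.1% lay in the same cluster. Of the 24 named genes, 21 of 22 with enough UMIs kept their direction among Xist cells and 21 of 23 among Y cells. They were named from all cells of the class, these included, so a kept direction is little evidence.

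**Figure D3:**
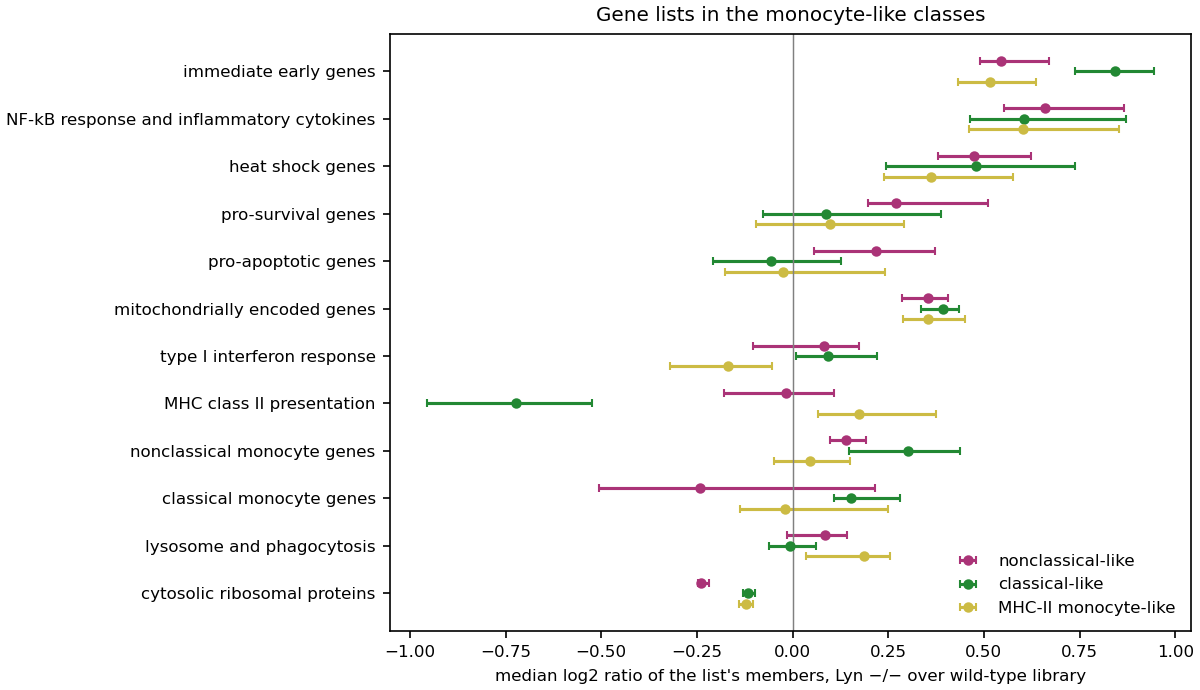
Median log2 ratio of the Lyn -/- over the wild-type library (horizontal axis) of 12 gene lists in the 3 monocyte-like classes; points are medians over measured members and bars are 95% intervals from Poisson resampling. Immediate early genes lie at 0.54 in nonclassical-like and 0.84 in classical-like cells.

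The last comparison set the genotype difference of nonclassical-like cells beside that of classical-like cells. The log2 ratio of Nr4a1 was 0.97 in nonclassical-like and 1.68 in classical-like cells, a difference of -0.71 (-0.88 to -0.54). Within donor kinds both ratios were lower, at 0.58 and 1.16 among Y cells. Among Xist cells the classical-like ratio was 1.53, and the nonclassical-like one is given above. Hpgd (-1.40 and -1.01), Cd74 (-1.16 and -1.14), Jun (1.30 and 1.15), Clec4e (1.44 and 1.58) and Hspa1a (3.15 and 3.23) lay on the same side in both classes. Within donor kinds Cd74 was less alike, at -0.82 and -2.62 among Xist cells and at -0.79 and -0.49 among Y cells. Hspa1b lay on the same side too, at 3.05 and 1.90, but with a difference of 1.15 (0.40 to 1.91). Ccr2, the chemokine receptor of classical monocytes, had log2 ratios of -0.85 and 0.15, a difference of -1.0 (-1.36 to -0.64), but in the nonclassical-like cluster with most Lyn -/- cells its log2 ratio was 0.11. Plac8 had log2 ratios of -0.54 and 0.43, a difference of -0.98 (-1.07 to -0.88). Across 2963 genes the log2 ratios of the 2 classes had a Pearson correlation of 0.431, and genes are not independent replicates. With no replicate libraries these differences between classes were not tested.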

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

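Chosen only after the result was seen were the tests of donor kinds for the share, the gene lists and single genes, of single clusters, of leaving out the 2% of cells with most UMIs, of handling, and of Nr4a1 in classical-like cells. The tests of the gene limit, of mitochondrial matching and of Nr4a1 in nonclassical-like cells were chosen before theirs.

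Cells with genes of other cell types were found among the deposited monocytes, outside the comparisons. A cluster with neutrophil genes held 5.89% of deposited Lyn -/- cells (4.75 to 7.21) and 0.913% of wild-type cells (0.368 to 1.87). A cluster with T cell genes held 1.88% (1.25 to 2.70) and 0.261% (0.0316 to 0.939). Clusters with platelet and B cell genes held 1.14% and 0.134% of Lyn -/- cells, and 0.261% and 1.04% of wild-type cells.

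Some genes had log2 ratios of opposite sign in nonclassical-like and classical-like cells, with 0 outside both intervals. The differences between the classes were not tested. As the nonclassical-like minus the classical-like log2 ratio, they were 4.17 for Lyz1, 1.51 for H2-Eb1, 1.10 for Trp53, -0.22 for Ifi27l2a, -0.98 for Plac8, -1.0 for Ccr2, -2.25 for Gm42418 and -2.81 for Ly6a. For all but Plac8 the sign turned in 1 or both classes under an alternative. In nonclassical-like cells Lyz1 was at -0.64, -0.98 and -0.88 and H2-Eb1 at -0.49 and -0.29 under other ways of forming the classes, and H2-Eb1 at -1.26 without the 2% of cells with most of its UMIs. In classical-like Y cells H2-Eb1 was at 0.028. Among nonclassical-like Y cells Trp53 was at -5.4e-05, Ifi27l2a at 0.79 and Ly6a at 0.92, and Ccr2 was at 0.11 in the cluster with most Lyn -/- cells. In classical-like cells 1 Lyn -/- cell held 53.8% of the Gm42418 UMIs, and without the 2% of cells with most of them Gm42418 was at -0.28.

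The higher nonclassical-like share of the Lyn -/- library was weighed first. A different mix of Xist and Y cells is argued against as the whole cause, because the smaller of the differences within Xist cells and within Y cells was 31.9 percentage points. Cells of neither kind were left out of that comparison. Loss of large classical-like and MHC class II cells at the limit on genes per cell stays open, because cells over the limit could not be counted. The Lyn -/- library held 58 such cells in the 200 genes under the limit and 65 in the 200 before, a ratio of 0.892 (0.615 to 1.29) whose interval holds 1. That ratio describes the cells kept and not those lost, so it cannot decide the question. The sort, the authors' choice of monocytes, the mix of single mice within a kind and the genotype stay open too, since each genotype had 1 library.

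The immediate early and NF-kB genes, higher in the Lyn -/- library, were weighed next. The mix of Xist and Y cells is argued against as the whole cause, since the lowest of 8 list medians within donor kinds was 0.51 (0.38 to 0.65). Those medians leave out cells of neither kind. RNA quality, as read from mitochondrially encoded UMIs, is argued against likewise, since the lowest of 4 medians after matching cells on that percentage was 0.57 (0.50 to 0.74). Handling and genotype cannot be told apart, because both would raise the lists in every class, and the lowest of 6 medians over the 3 classes was 0.52. They cannot be told apart for the heat shock genes either. Those medians were 0.47 in nonclassical-like, 0.48 in classical-like and 0.36 in MHC class II cells, but -0.16 among classical-like Xist cells. The genotype and the mix of single mice within a kind stay untested explanations.

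The higher Nr4a1 of the Lyn -/- library was weighed last, because the reporter donors carry a transgene named for this gene. Reporter transcripts counted as Nr4a1 are argued against as the whole cause, since in Y cells, nearly without reporter UMIs, the log2 ratio was 1.16 (0.77 to 1.56) in classical-like and 0.58 (0.37 to 0.80) in nonclassical-like cells. The pooled values were 1.68 and 0.97, and part of the latter may come from the larger share of Xist cells among nonclassical-like cells, 47.5% in the Lyn -/- and 26.8% in the wild-type library. Handling and genotype stay open here as well.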

How the results depend on the processing

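Xist cells, Y cells, single nonclassical-like clusters, leaving out the 2% of cells with most UMIs of a gene, and the scaled scores were tests chosen only after the result was seen. Of 5369 values under all alternatives, 4700 were counted as unchanged, 596 as moved and 73 as reversed. Unchanged values stayed within their main counting interval, and reversed ones changed sign where that interval left out 0. A change of sign from an interval that held 0 was counted as unchanged or moved. The unchanged values include 316 scaled scores, which were read for direction only. Overlaps of named genes, also among the values, were judged by the number of genes shared. Doublet removal and the filter on cells moved none of 322 values each, but both left out few cells, so little movement was possible. The filter asked for at least 500 genes, at least 1000 UMIs and at most 10% mitochondrially encoded UMIs. It left out 1 wild-type and 4 Lyn -/- cells, and doublet removal 13 and 11. Lyn stayed below 0 in each alternative that gave it a value. Unless stated, the cause was not tested. In what follows N stands for nonclassical-like and C for classical-like cells, and values are log2 ratios or list medians. With TMM factors, N gave Rps20 -0.021, pro-survival 0.19 and immediate early genes 0.46, and with DESeq2 size factors -0.026, 0.18 and 0.46. With 5 UMIs added the N NF-kB median was 0.55. With list members of at least 200 UMIs, fewer genes entered. In N immediate early genes were then at 0.48 and neutrophil genes at -0.0017, and in C immediate early genes at 0.65, heat shock genes at 0.20 and chemokine receptors at -0.19. Thinning cells to 2500 UMIs left out 84 wild-type and 143 Lyn -/- cells, and in C gave H2-T23 0.074, Ccr1 -0.18 and chemokine receptors -0.14. Leiden resolution 0.3 gave N Lyz1 -0.64, C C1qb 0.67 and C immediate early genes 0.72, with nonclassical-like shares of 49.9% (wild-type) and 83.1% (Lyn -/-). At that resolution the MHC class II class and the cluster with platelet genes did not form. Resolution 1.0 gave C interferon genes -0.010 and immediate early genes 0.71. Placement by markers gave N Lyn -5.97, H2-Eb1 -0.49, Phf11d -0.0048, Lyz1 -0.98 and immediate early genes 0.72, C C1qb 0.30, and shares of 52.4% and 85.0%. It also placed cells of the clusters with genes of other cell types, which the main shares leave out. Clustering without differing genes gave N H2-Eb1 -0.29 and Lyz1 -0.88, C C1qb 0.68 and immediate early genes 0.71, and shares of 53.8% and 84.0%. There the clusters with platelet, T cell and B cell genes did not form. Over all deposited cells the Lyn -/- share was 73.1%. Among Xist cells N gave Ccl5 0.0014, H2-K1 -0.16, Slc16a3 -0.21, Gapdh 0.026, Rps20 -0.015, pro-survival 0.19, heat shock 0.34, oxidative phosphorylation 0.022 and genes near Lyn -0.016. There C gave Lyn -5.71, Thbs1 -0.44, Pmaip1 -0.47, Hspa1b -1.19, Hsp90aa1 -0.16, Cd44 -0.13 and mt-Nd2 -0.0081. The C medians there were -0.30 for pro-apoptotic, 1.13 for NF-kB and -0.16 for heat shock genes, and the Lyn -/- share was 85.3%. Among Y cells N gave Fcgr3 0.027, Ly6a 0.92, Fgr -0.019, Fas -0.75, Trp53 -5.4e-05, Ifi27l2a 0.79 and S100a8 -0.61. The N medians there were 0.68 for immediate early, 0.90 for heat shock, -0.022 for Fc receptor and -0.18 for neutrophil genes. In C, Y cells gave Gm42418 -0.049, H2-Eb1 0.028, Cfp 0.12, inhibitory receptors -0.0040, heat shock 1.05 and chemokine receptors -0.094, and the Lyn -/- share was 73.8%. The N cluster with most wild-type cells gave Lyn -6.54, Cblb -0.11, Ptpn6 -0.016, H2-Eb1 -0.072, Ifih1 -0.082, Ccl3 -0.31, Il13ra1 0.21, Spred1 -0.071, Gapdh 0.041 and Apoe 0.11. Its medians were -0.12 for inhibitory receptors, -0.0028 for nonclassical, 0.36 for NF-kB and 0.040 for oxidative phosphorylation genes. The N cluster with most Lyn -/- cells gave Ccl5 0.13, Bcl2a1a -0.040, Ccr2 0.11, Slc16a3 -0.0095, Pfkfb3 -0.073, Apoe 0.11 and S100a8 -0.42. Its medians were 0.048 for pro-survival, 0.34 for NF-kB, 0.37 for immediate early, 0.0048 for oxidative phosphorylation and -0.29 for neutrophil genes. Without the 2% of cells with most UMIs, N H2-Eb1 was -1.26 and C Gm42418 -0.28, a setting that removes the cells richest in them. The scaled scores, read for direction only, gave N H2-Eb1 -0.055, Lyz1 -0.025 and oxidative phosphorylation 0.0020, and C Gm42418 -0.36. The rule for named genes with at least 400 UMIs shared 17 of 24 genes in N and 10 in C. Genes with under 20 UMIs, or with 0 in a library, under an alternative gave no value. No paired analysis was possible because each genotype had 1 library. Depth limits the donor kinds of classical-like cells, with 61 and 39 Xist cells and 89 and 52 Y cells in the wild-type and Lyn -/- libraries, and those of the MHC class II class, with 40 and 20 Y cells.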

Other observations

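The MHC class II class, with 161 wild-type and 113 Lyn -/- cells, was too small for the main comparisons. In it Clec4e (log2 ratio 1.71, 1.14 to 2.33), Hspa1a (2.17, 1.54 to 2.88) and Lpl (1.74, 1.18 to 2.35) were higher in the Lyn -/- library, as in nonclassical-like cells. Dusp2 (1.37) and the tetraspanin Cd9 (1.34) were higher too. Lower were Dusp6 (-1.46, -1.87 to -1.08), the receptor Notch2 (-1.18, -1.62 to -0.77) and Serpinb2 (-1.24, -1.86 to -0.69). Lipid handling genes had a median of 0.34 (0.099 to 0.59, percentile 99.96), and type I interferon genes one of -0.17 (-0.32 to -0.053), but 0.24 among Y cells. Hmox1, haem oxygenase, had a log2 ratio of 1.23 over all cells, 2.86 among Xist cells and -2.88 among Y cells, but 1 wild-type cell held 58.0% of its 226 wild-type UMIs in the class.

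Nr4a1 also differed between kinds of donor cells within each library. In nonclassical-like cells the log2 ratio of Xist cells over Y cells was 2.06 in the wild-type and 2.08 in the Lyn -/- library, and in classical-like cells 2.08 and 2.45. Sex and reporter cannot be separated in this comparison. Xist cells made up 27.5% of monocyte-like cells in the wild-type library and 44.7% in the Lyn -/- library. Across genes the SD of the Xist over Y log2 ratio in nonclassical-like cells was 0.50 in the wild-type and 0.42 in the Lyn -/- library. That of the ratio between the libraries was 0.36. These SDs include counting error and rest on unlike depths. Wild-type Xist and Y cells of the class held 341203 and 348715 UMIs, and Lyn -/- ones 2185570 and 823592. All cells of the class held 1179371 and 4334803. Sex-linked genes were not left out. The SDs therefore do not rank donor kinds against libraries.

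Complement genes had a median of 0.77 in nonclassical-like cells over 5 measured members, with C3 at 0.77 (0.43 to 1.14). Nonclassical monocyte genes had a median of 0.14 there and 0.30 in classical-like cells. PI3K, AKT, FOXO and MAPK feedback genes had one of 0.22 and 0.057, and oxidative phosphorylation genes one of -0.039 and -0.052. Glycolysis genes had one of 0.0022 and 0.13, and lysosome genes one of 0.085 and -0.0056, each with an interval that held 0. In classical-like cells the intervals of the feedback and oxidative phosphorylation lists held 0 too. There the glycolysis median was -0.0040 among Xist cells and -0.23 among Y cells.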
